A study of Mus musculus with 12 samples.

How the data were processed

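Tumours were taken from 3 FVB MMTV-PyMT mice aged 10 weeks and digested with collagenase I and DNase, per the labels. Live cells negative for CD45, CD31 and EPCAM and positive for PDGFRb were sorted by Ly6C, CD146, PDGFRa and NCAM into 4 populations, here called icaf, m2cafneg, m2cafpos and vcaf as in the labels. RNA was purified with a column kit for small samples and the libraries were sequenced on an Illumina NovaSeq instrument. There were 12 libraries, 1 per population and mouse. A library titled 27_vacf was read as vcaf of mouse 27, since each other mouse has a library of that name and the table has a column for it. The submitters' processing notes name bcl2fastq, DRAGEN and the mouse genome mm10 with no versions. The library kit, the counting tool, its handling of strand and of reads that fit more than 1 gene, the annotation release and any filter are not given in the sources used here. Values of antisense or overlapping genes and of close paralogs (Ly6c1 and Ly6c2, or Serpina1b and its family) are therefore less certain than those of other genes.

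The deposited table holds CPM (counts per 1000000 reads assigned to genes) for the 12 libraries, made by the authors. It has 55774 lines, of which 287 repeat a gene identifier with the same values (0 differ), which left 55487 genes. Over these, each column sums to 1000000, so the authors divided reads by the total assigned to genes and applied no other scaling between libraries. Every value was a whole multiple of a single read within 0.001 reads (100% of values in each library), and this gave the reads per gene and the totals of 43898839 to 55363203 per library. A read stood for 0.0181 to 0.0228 CPM, and a count of 0 was taken to allow up to 3 reads. Such floors cover counting error only, since reads were not marked by molecule. In all, 19288 genes had no read in any library. Positions were taken from the GENCODE M21 annotation on GRCm38, which held 99.5% of the gene identifiers, 96.7% of them under the same symbol. A symbol was shared by more than 1 identifier for 234 genes, and these were kept apart by identifier, also as list members.

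Genes with at least 1 CPM in at least 3 libraries were kept (15456 genes). Values were compared as log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend, two-sided), with 4 groups of 3 libraries, 8 residual and 4.29 prior degrees of freedom. Because 1 CPM is added, fold changes of genes near or below 1 CPM are understated. P values were adjusted by the Benjamini-Hochberg method over the kept genes within each comparison, with a threshold of 0.05. The 3 main comparisons were vcaf against the mean of the other 3 populations, icaf against the mean of m2cafneg and m2cafpos, and m2cafpos against m2cafneg, and the other 5 pairs of populations were compared as well. A gene was counted as specific to a population when it was higher against each of the other 3. These choices, the gene lists and the rule for naming genes were fixed before the data were examined.

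The gene lists numbered 34 and held 554 members, of which 1 matched no gene (Ahsp) and 64 fell below the filter. They comprised 23 lists of programmes and sample quality, 10 of other cell types that a sort could let through, and the genes of the sort itself. Each was tested in the 3 main comparisons with camera of limma at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. Members were counted as higher, lower or not past the test, over all genes and adjusted over the list alone. Of the calls at the preset correlation, those of the fibrillar collagen, matrix remodelling, matricellular, universal Pi16 fibroblast, BMP and Wnt and growth factor lists in vcaf held with an estimated correlation, and the other 41 of 47 did not.

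Genes named were chosen by rule. For each main comparison these were the 10 with the largest higher and the 10 with the largest lower log2 fold change among genes past the threshold, with a mean of at least 10 CPM on the higher side and no overlap between the libraries of both sides, which chance gives for 10% of genes in a comparison of 3 against 3 libraries. Gene models known only by a number were left out. From each list called by camera or with at least 3 members past the test, up to 4 members with the smallest adjusted p were named, and 5 genes per population among the specific genes. The sort genes, Cdkn2a, Cdkn1a, Acta2, Il6 and Col1a1 were always named, with the 2 most abundant members of each list of another cell type. Cdkn2b was followed into the pairwise comparisons, and the transcription factors and receptors in the last part were chosen, after their values were seen. Some genes that the rule names are not reported here.

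Mouse numbers recur in all 4 populations, and they were checked as names of animals. Across genes, the deviations of 2 libraries from their population means were correlated with a median r of 0.293 (0.0843 to 0.452) for the 18 pairs from the same mouse and -0.149 (-0.363 to 0.0746) for the 36 other pairs, and for 12 of 12 libraries the closest library came from the same mouse. Genes are not independent replicates in these correlations. The reported values come from the fit without the mouse, as planned, and a fit with the mouse as a block was run beside it. It changed the values of Epcam and Pecam1 in the icaf comparison, Ly6c1 in m2cafpos against m2cafneg and the count of genes specific to m2cafneg as printed with those results. Genes called rose with it from 10431 to 10933 in the vcaf comparison, 4063 to 5099 in icaf and 4041 to 5128 in m2cafpos against m2cafneg.

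The alternatives set beforehand were median-of-ratios scaling of the CPM values, pseudocounts of 0.1 and 5, no filter and a filter at 5 CPM in 3 libraries, the mouse as a block, limma without the trend, a log2 fold change of at least 1, fits of only the 2 groups compared, an estimated correlation for camera, and leaving out each library in turn. Where a population was left with 2 libraries, these were taken to vary like the others. Chosen after seeing the data were the edgeR 4.0.16 quasi-likelihood test (common dispersion 0.0728, normalization factors 0.849 to 1.25), the same with the mouse as a block, DESeq2 1.42.0, the mean log2(CPM + 1) of the epithelial list as a covariate, that covariate with median-of-ratios scaling, and a fit of mice 27 and 30 only, since the epithelial score was highest in mouse 31 in each population. The count-based tests were run on the recovered reads.

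The fits were tested on simulated data in which 100 genes were changed by 2-fold and 100 by 4-fold. In the vcaf, icaf and m2cafpos comparisons limma recovered 100% of the 4-fold changes and 71%, 44% and 25% of the 2-fold changes, with 7.07%, 2.70% and 6.72% of calls false. For edgeR the 2-fold shares were 65%, 49% and 25% with 5.17%, 2.61% and 7.41% of calls false, and for DESeq2 72%, 54% and 42% with 13.6%, 9.41% and 11.3% false. These shares of false calls do not carry over to the data, where 26.1% to 67.5% of genes were called in the main comparisons. Of 50 simulated lists of unchanged genes camera called 0 in each comparison at the adjusted threshold, and it called the list that was shifted. Members were uncorrelated there, while estimated correlations in the data reached 0.851 (proliferation) and 0.750 (epithelial). The simulation therefore does not test false calls in lists with correlated members. Other splits of the libraries were counted with 100 draws, again with 100 draws that kept each population once in each mouse, or with all 10 splits for 3 against 3 libraries. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.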

Results

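RNA was sequenced from stromal cells sorted out of spontaneous mammary tumours of 3 FVB MMTV-PyMT mice, a strain in which a viral promoter drives the polyoma middle T oncogene in mammary epithelium. From each tumour, live cells negative for CD45, CD31 and EPCAM and positive for PDGFRb were divided into 4 populations of cancer-associated fibroblasts, per the labels. The icaf gate took Ly6C-positive cells. The vcaf gate took Ly6C-negative, CD146-positive, PDGFRa-negative cells. The m2cafneg and m2cafpos gates took Ly6C-negative, CD146-negative, PDGFRa-positive cells that were NCAM-negative or NCAM-positive. Each population had 3 libraries, 1 per mouse (27, 30 and 31), which gave 12 libraries of 43898839 to 55363203 reads assigned to genes. A single read stood for 0.0181 to 0.0228 CPM (counts per 1000000 reads assigned to genes), and between 13413 and 14767 genes reached 1 CPM in a library. The series title concerns senescent stroma and immunosuppression in breast cancer, and the design compares expression among the 4 populations. In all values below n = 3 libraries per population, errors are SD for CPM and SE for log2 fold changes, and positions are on GRCm38 (mm10).

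Transcripts of Ly6C, CD146, NCAM and PDGFRa were highest or lowest in the populations gated on these proteins, while those of EPCAM and CD31, which were gated out, were measured in all 4 populations. Ly6c1 (ENSMUSG00000079018, chromosome 15, 75044018 to 75048830), which encodes a Ly6C antigen, stood at 1106 ± 140.0 CPM in icaf and at 66.3 ± 13.9 in m2cafneg, 43.7 ± 16.6 in m2cafpos and 31.3 ± 11.8 in vcaf. Its neighbour Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), a close paralog, stood at 39.0 ± 2.91 CPM in icaf and at most 2.61 ± 0.254 elsewhere. Mcam (ENSMUSG00000032135, chromosome 9, 44134469 to 44142727), which encodes CD146, stood at 269 ± 25.1 CPM in vcaf against 3.44 ± 2.66 in icaf, 9.82 ± 8.67 in m2cafneg and 4.16 ± 1.83 in m2cafpos. Ncam1 (ENSMUSG00000039542, chromosome 9, 49502136 to 49798925) stood at 585 ± 20.3 CPM in m2cafpos and 31.1 ± 5.63 in m2cafneg. Ncam1 also reached 96.5 ± 12.2 CPM in icaf, a population that was not sorted on NCAM. Pdgfra (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215) lay between 403 ± 44.8 and 537 ± 61.0 CPM in the 3 other populations and at 6.73 ± 2.07 in vcaf. Pdgfrb (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061) was lowest in icaf, at 188 ± 42.5 CPM, and highest in vcaf, at 2105 ± 242. Among transcripts of the proteins sorted against, Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129) was measured at 546 ± 171 CPM in vcaf, 380 ± 124 in m2cafneg, 73.7 ± 47.9 in m2cafpos and 71.3 ± 38.3 in icaf. Pecam1, which encodes CD31, stood at 69.4 ± 25.5 CPM in vcaf and 39.97 ± 31.0 in m2cafneg, and Ptprc, which encodes CD45, stayed at 4.83 ± 1.78 CPM or lower.

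**Figure D1:**
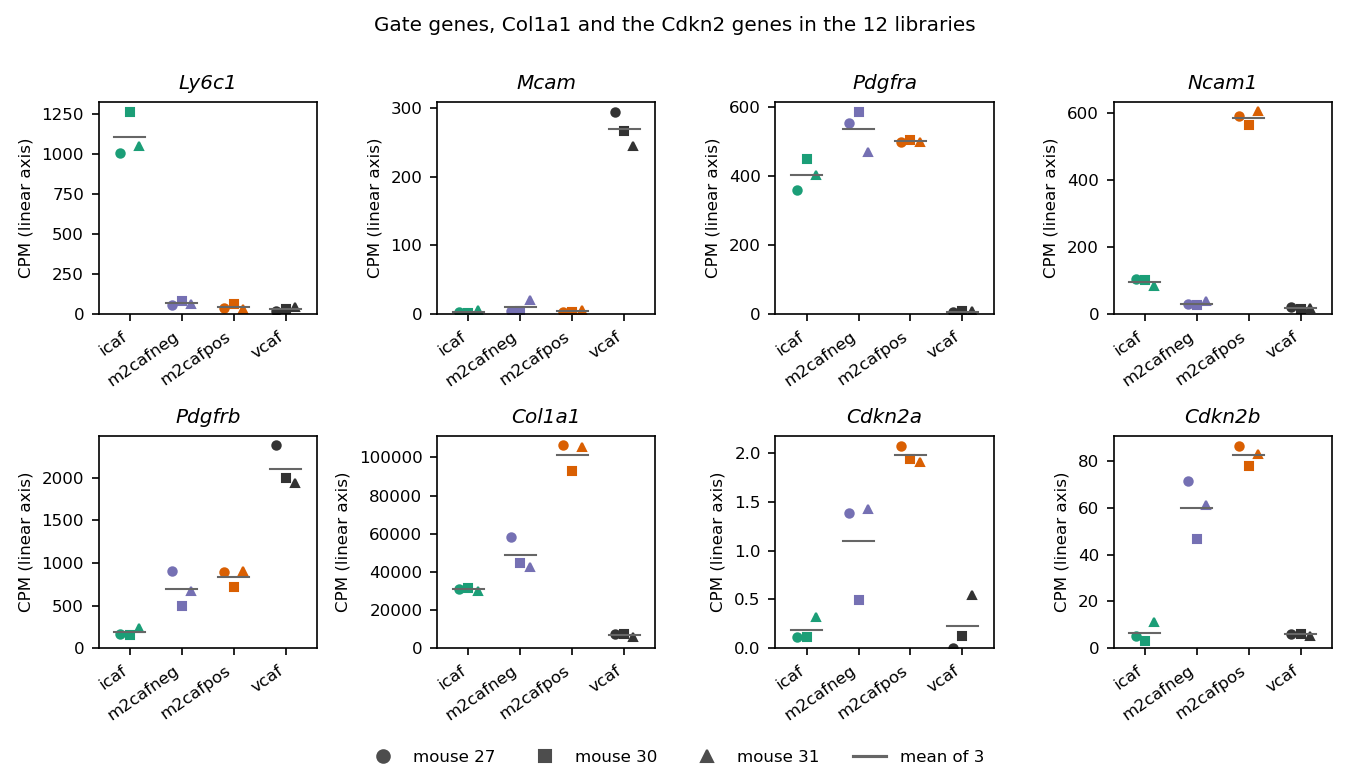
Expression of the sort genes Ly6c1, Mcam, Pdgfra, Ncam1 and Pdgfrb and of Col1a1, Cdkn2a and Cdkn2b in each library. Values are in CPM on linear axes, by population, with 1 symbol per mouse and a line at the mean of 3 libraries. Ly6c1 is highest in icaf (mean 1106 CPM), Mcam in vcaf (269) and Ncam1 in m2cafpos (585).

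Libraries were on average most alike within a population. Across genes, mean Pearson r within a population lay between 0.976 in m2cafneg and 0.985 in m2cafpos, while icaf and vcaf were least alike (0.831) and m2cafneg and m2cafpos most alike (0.955). The lowest r within m2cafneg (0.972) was below the highest between m2cafneg and m2cafpos (0.973). Genes are not independent replicates in these correlations. The m2cafneg libraries were closer to vcaf (0.890) than the m2cafpos libraries were (0.845). In m2cafpos, Col1a1 alone took 10.1% of reads and the 10 most abundant genes took 22.6%, against 12.5% to 14.5% for the 10 most abundant genes in the other populations.

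**Figure D2:**
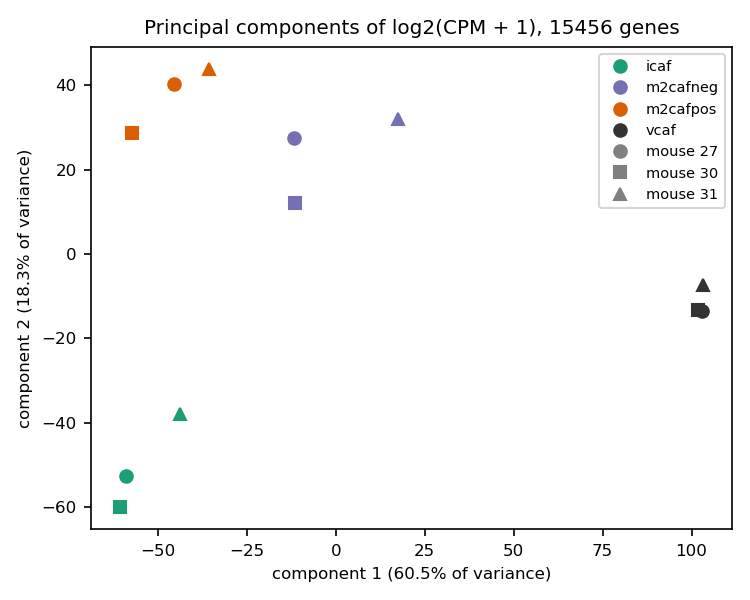
Principal components of the 12 libraries from log2(CPM + 1) values, with component 1 (60.5% of variance) on the horizontal axis and component 2 (18.3%) on the vertical axis, coloured by population with 1 symbol per mouse. The vcaf libraries separate from the other 9 libraries along component 1.

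Transcripts typical of other cell types were unevenly spread over the gates. The summed CPM of 20 epithelial genes was 13757 in vcaf, 10052 in m2cafneg, 2143 in icaf and 2105 in m2cafpos, with the milk protein gene Csn3 the most abundant (5252, 4222, 920 and 875 CPM). The sum of 18 macrophage and monocyte genes was 1175 CPM in vcaf, 871 in m2cafneg, 172 in icaf and 201 in m2cafpos. Cd14 led it (750, 504, 88.3 and 106 CPM). Endothelial genes summed to 1589 CPM in vcaf, 614 in m2cafneg, 509 in icaf and 276 in m2cafpos. Part of the vcaf sum came from Esam (557 CPM) and Eng (328 CPM). Neutrophil genes summed to 1347 CPM in vcaf and 1163 in m2cafneg, nearly all from Ltf (1331 and 1151 CPM), which is also a milk protein gene, and to 306 in icaf, of which 135 came from Il1r2. Schwann and nerve genes were highest in icaf at 934 CPM, of which Pmp22, expressed in many mesenchymal cells, gave 737. Sums by population ranged over 344 to 793 CPM (adipocyte), 15.4 to 134 (lymphocyte), 4.70 to 54.6 (skeletal muscle) and 32.5 to 94.9 (erythroid). The mesothelial sum (68.3 to 385) was mostly the keratin gene Krt19 (64.3 to 384), high where epithelial sums were.

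**Figure D3:**
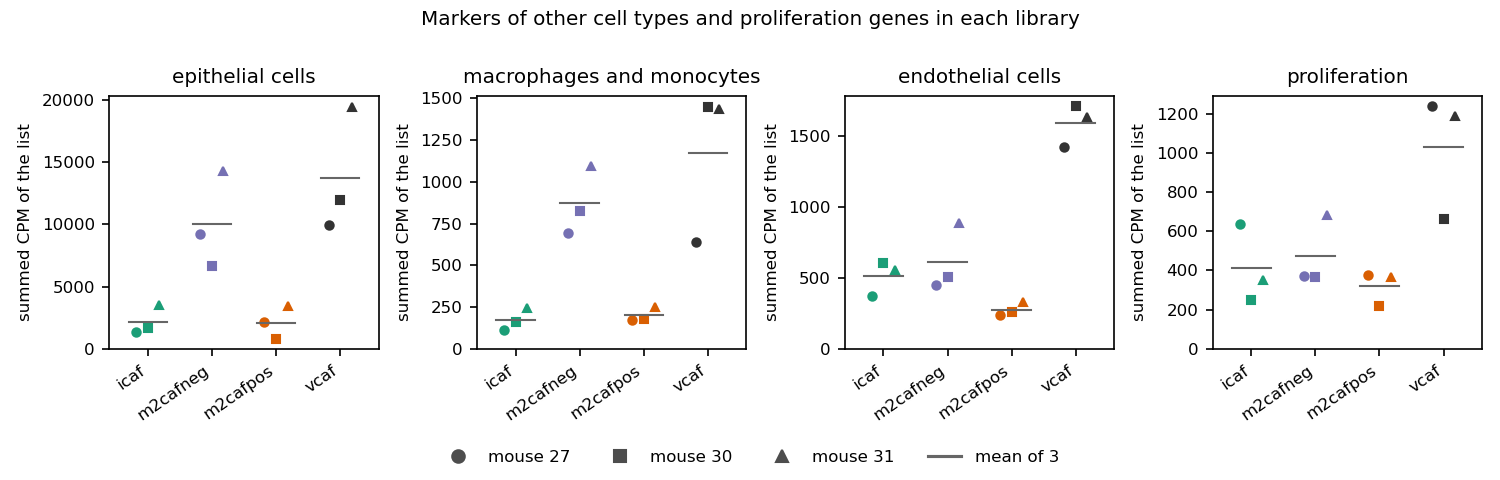
Summed CPM of marker genes of other cell types in each library, on linear axes, by population, with 1 symbol per mouse and a line at the mean of 3 libraries. Epithelial and macrophage sums are higher in vcaf (13757 and 1175 CPM) and m2cafneg (10052 and 871) than in icaf (2143 and 172) and m2cafpos (2105 and 201).

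The vcaf libraries carried the genes of pericytes and vascular smooth muscle at levels far above the other 3 populations and fibroblast matrix genes at lower levels than those populations. Rgs5 (ENSMUSG00000026678, chromosome 1, 169655501 to 169695813), a regulator of G-protein signalling and a pericyte marker, was the most abundant gene in vcaf at 41419 ± 10177 CPM against 87.9 ± 105 over the 9 other libraries, a log2 fold change of 9.40 (SE 0.58, limma adjusted p = 5.20e-08). The intermediate filament gene Des rose by 7.27 (SE 0.39, adjusted p = 1.54e-08), the gap junction gene Gja4 by 7.48 (SE 0.53, adjusted p = 1.67e-07) and the receptor gene Notch3 by 6.12 (SE 0.31, adjusted p = 8.20e-09). In the other direction, the small proteoglycan genes Dcn (-6.04, SE 0.28, adjusted p = 3.81e-09) and Lum (-5.90, SE 0.15, adjusted p = 5.67e-11) and the adventitial fibroblast marker Pi16 (-6.16, SE 0.28, adjusted p = 3.71e-09) were lower in vcaf. The comparison asks how the perivascular gate differs from the mean of the 3 other gates, per the gate markers in the labels.

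Further genes with large differences were of several kinds. Higher in vcaf by 6.82 to 8.22 on the log2 scale were Higd1b and Cox4i2, mitochondrial protein genes of pericytes, the integrin gene Itga7, the Ras-like gene Rasl12, the trafficking gene Trarg1, the olfactory receptor gene Olfr558 and the serpin gene Serpina1b, whose close paralogs share sequence. Lower in vcaf, at -5.51 to -6.26, were Dpep1, a dipeptidase gene, Mmp3, a stromelysin gene, Pdgfra, the enkephalin gene Penk, the Wnt antagonist gene Sfrp4, Cpxm1 and the microfibril gene Mfap5. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590), which encodes smooth muscle actin, was measured at 1921 ± 79.4 CPM in vcaf, 218 ± 69.7 in m2cafpos, 63.5 ± 34.5 in m2cafneg and 39.6 ± 18.5 in icaf (log2 fold change 4.64, SE 0.35, adjusted p = 2.80e-07). Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), an inflammatory cytokine gene, was also highest in vcaf at 106 ± 21.9 CPM (1.93, SE 0.19, adjusted p = 3.44e-06). Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) was lowest in vcaf at 6882 ± 1037 CPM (-2.96, SE 0.24, adjusted p = 7.25e-07). Among cell cycle inhibitor genes, Cdkn2b (-2.24, SE 0.24, adjusted p = 7.70e-06) and the weakly expressed Cdkn2a (-0.68, SE 0.18, adjusted p = 0.00471) were lower in vcaf. Cdkn1a was higher by 0.43 (SE 0.12, adjusted p = 0.00709), a call that ended with median-of-ratios scaling (0.01), with edgeR (adjusted p = 0.851) and without the vcaf library of mouse 27 (adjusted p = 0.0545).

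Adjusted p values of camera are given at the preset correlation and, where 2 values stand together, then with an estimated correlation between genes. All 18 pericyte genes were higher in vcaf (median log2 fold change 5.24, camera adjusted p = 7.96e-09), as were 14 of 15 vascular smooth muscle genes with 1 not past the test (median 4.38, camera adjusted p = 7.88e-07). With an estimated correlation the camera adjusted p was 0.0711 for the pericyte list and 0.0602 for the smooth muscle list. Their members included the calsequestrin gene Casq2 (log2 fold change 5.84), the smooth muscle actin gene Actg2 (5.87) and the G-protein regulator gene Rgs4 (5.66). Of 15 myofibroblast contractile genes 13 were higher and 2 lower (camera adjusted p = 0.000194 preset, 0.265 estimated). Members included Myl9 at 4.58 and Mylk at 5.33. Of 12 Notch genes 10 were higher, 1 lower and 1 not past the test, including the targets Hey2 (3.55) and Hes1 (1.31) and the ligand Jag1 (1.51). Its camera adjusted p was 0.0466, adjusted p = 0.414 with an estimated correlation, and the call ended with the epithelial covariate (4 genes higher, 0.255) and without icaf 27 (0.0554), icaf 30 (0.0504), m2cafneg 27 (0.0522), m2cafpos 27 (0.0559), m2cafpos 30 (0.0512), vcaf 27 (0.0910), vcaf 30 (0.0919) or vcaf 31 (0.129), each named by population and mouse. Counts of higher genes adjusted over the list alone were 18 pericyte, 14 smooth muscle, 13 contractile and 10 Notch genes. Of 20 endothelial genes 16 were higher, 2 lower and 2 not past the test (camera adjusted p = 0.0981 preset, 0.568 estimated). With the epithelial covariate 5 endothelial genes were higher and 1 lower, against 17 pericyte and 13 smooth muscle genes higher.

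Fibroblast programmes were lower in vcaf. Of 20 fibrillar collagen and assembly genes 18 were lower, 1 higher and 1 not past the test (median -2.21, camera adjusted p = 1.91e-18 preset, 0.00972 estimated), among them Loxl1 (-4.23), Lox (-4.13), which encode collagen cross-linking enzymes, and Col14a1 (-5.12). Of 20 matrix remodelling enzymes 15 were lower, 4 higher and 1 not past the test (camera adjusted p = 1.96e-10 preset, 0.00972 estimated). Members included Mmp2 at -4.27 and Mmp19 at -4.63. Of 21 matricellular and TGF-beta response genes 13 were lower, 4 higher and 4 not past the test, with Thbs2 at -3.16 and Cthrc1 at -4.86 (camera adjusted p = 7.96e-09 preset, 0.0394 estimated), and with median-of-ratios scaling 14 were lower and 0 higher. Of 15 genes of the universal Pi16 fibroblast list 13 were lower and 2 not past the test (median -3.31, camera adjusted p = 9.71e-14 preset, 0.0394 estimated). Of 26 BMP and Wnt genes 17 were lower, 5 higher and 4 not past the test, led by the Wnt antagonist genes Sfrp2 (-4.90) and Dkk3 (-2.01) and the ligand gene Wnt2 (-5.19), with a camera adjusted p of 8.23e-09 and adjusted p = 0.00841 with an estimated correlation. Of 21 growth factor genes 11 were lower, 5 higher and 5 not past the test (camera adjusted p = 6.06e-05 preset, 0.0362 estimated). Members included Igf1 at -4.71 and Fgf7 at -3.86 against Pdgfa at 3.90 and Angpt2 at 2.72. The lower members of these 6 lists adjusted over the list alone numbered 18, 15, 14, 13, 18 and 11. Inflammatory CAF genes (11 of 19 lower, 4 higher, 4 not past the test) included Cxcl14 (-4.84) and Dpt (-4.81), with a camera adjusted p of 1.42e-06 and adjusted p = 0.0711 with an estimated correlation. Complement genes (9 of 16 lower, 5 higher, 2 not past the test) included C3 (-3.97) and C4b (-2.86), with a camera adjusted p of 5.73e-05 and adjusted p = 0.135 with an estimated correlation. Chemokine and cytokine genes (11 of 21 lower, 5 higher, 5 not past the test) included Il33 (-4.71) and Csf1 (-2.74), with a camera adjusted p of 6.84e-05 and adjusted p = 0.157 with an estimated correlation. There were 12 inflammatory CAF, 9 complement and 12 chemokine genes lower when adjusted over the list alone.

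In several lists most members were higher in vcaf beside the markers of other cells, and of the programme lists among them only proliferation was called by camera, at the preset correlation alone. Of 26 proliferation genes 25 were higher and 1 not past the test, with the kinetochore motor gene Cenpe at 1.84 (SE 0.23) and the replication helicase gene Mcm6 at 1.71 (SE 0.30), limma adjusted p = 3.13e-05 and 0.000370. All 20 epithelial genes and all 17 macrophage genes tested were higher too. The camera adjusted p of the proliferation list was 0.00809, adjusted p = 0.568 with an estimated correlation, and with median-of-ratios scaling 20 of the 26 genes were higher. The epithelial list had a camera adjusted p of 0.0135 (adjusted p = 0.568 with an estimated correlation, and 0.0569 at the preset correlation without the vcaf library of mouse 31) and the macrophage list 0.00207 (adjusted p = 0.414 with an estimated correlation). Of 9 genes of the MHC class II list, which holds Slpi and Saa3 beside class II genes, 8 were higher and 1 not past the test. Among them were Cd74 (1.88) and H2-Ab1 (1.93), genes abundant in macrophages (camera adjusted p = 0.0510 preset, 0.480 estimated). Hypoxia and glycolysis genes (17 of 21 higher, 1 lower, 3 not past the test, camera adjusted p = 0.104 preset, 0.552 estimated) and dissociation stress genes (13 of 16 higher, 3 not past the test, camera adjusted p = 0.0781 preset, 0.513 estimated) were higher in smaller numbers with median-of-ratios scaling, at 9 and 6. Adjusted over the list alone 25 proliferation, 8 MHC class II, 18 hypoxia and 13 stress genes were higher.

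In other lists the members went both ways. Of 20 cell cycle arrest and senescence genes 12 were higher and 8 lower, with the cyclin gene Ccnd1 at 2.54 against Igfbp4 at -2.53, and the median (0.49) and the mean (0.05) were positive while the test pointed lower (camera adjusted p = 0.222 preset, 0.480 estimated). With median-of-ratios scaling 7 were higher and 8 lower, with a median of 0.07. Of 28 secretory phenotype factors 12 were lower, 11 higher and 5 not past the test (camera adjusted p = 0.00125 preset, 0.135 estimated). Members included Mmp10 at -3.59 and Hgf at -2.80, and with median-of-ratios scaling 13 were lower and 7 higher. The MHC class I and interferon list had 9 of 25 genes higher and 6 lower, with Irf1 at 0.93 and B2m at -0.43, a median of 0.07 and a mean of -0.04, and with median-of-ratios scaling 2 were higher and 10 lower and the median was -0.29. Its camera adjusted p was 0.0466, pointing lower, adjusted p = 0.480 with an estimated correlation, and 0.0591 without the m2cafpos library of mouse 31, 0.0665 without vcaf 30 and 0.0835 without vcaf 31. Of 18 genes for ligands that act on NK and T cells 6 were higher and 6 lower, with Nectin2 at 1.64 and the co-stimulatory ligand gene Cd80 at -1.26, and with median-of-ratios scaling 3 were higher and 10 lower. Its camera adjusted p was 0.0466, adjusted p = 0.265 with an estimated correlation, a call that ended without icaf 31 (0.0508), m2cafneg 31 (0.0672), m2cafpos 27 (0.0537), vcaf 27 (0.0758) or vcaf 30 (0.0832). Basement membrane genes went both ways (8 of 19 higher, 7 lower), with Col4a1 at 1.89 and Lama2 at -1.65, a median of 0.01 that was -0.41 with median-of-ratios scaling, and a test that pointed lower (camera adjusted p = 0.117 preset, 0.480 estimated). Chondro-osteogenic genes were also mixed (5 of 15 higher, 6 lower, camera adjusted p = 0.0164 preset, 0.264 estimated), with Cilp at -5.27 and Ogn at -5.23. With median-of-ratios scaling the camera calls of the secretory, NK and T cell ligand and chondro-osteogenic lists ended. For these 6 lists the higher and lower counts adjusted over the list alone were 12 and 8, 11 and 12, 9 and 6, 6 and 6, 8 and 7, and 5 and 6.

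In total 10431 of 15456 genes differed between vcaf and the mean of the other populations in limma (adjusted p under 0.05), 8238 higher and 2193 lower, and 3452 of them by at least 2-fold. With median-of-ratios scaling, which moved the median log2 fold change of all genes from 0.38 to 0.01, the split was 3566 higher and 3852 lower, so fold changes below about 0.38 in vcaf are within that shift. With the epithelial marker score as a covariate 4335 genes passed, and the camera calls of the proliferation (adjusted p = 0.172), MHC class I and interferon (0.0544) and Notch lists ended.

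Genes higher in icaf than in the other 2 PDGFRa-positive populations included genes known from adventitial fibroblasts and complement genes, and the camera calls of both lists were lost with an estimated correlation. The complement gene C3 was at 2708 CPM in icaf against 213 over the 6 m2cafneg and m2cafpos libraries (log2 fold change 3.74, SE 0.19, limma adjusted p = 2.00e-07). The peptidase gene Dpp4 (3.596, SE 0.24, adjusted p = 9.81e-07) and the semaphorin gene Sema3c (4.78, SE 0.22, adjusted p = 1.85e-07), both known from adventitial fibroblasts, were higher as well. Lower in icaf were the collagenase gene Mmp13 (-5.29, SE 0.52, adjusted p = 1.41e-05), the anchoring fibril gene Col7a1 (-4.47, SE 0.24, adjusted p = 2.41e-07) and Lrrc15 (-3.24, SE 0.31, adjusted p = 1.28e-05), a marker of TGF-beta-driven fibroblasts in tumours. The comparison asks how Ly6C-positive stroma differs from the mean of the Ly6C-negative, PDGFRa-positive gates.

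Other genes with the largest differences were, on the higher side at 4.37 to 5.57, Tubb4a, Smpd3, the scavenging chemokine receptor gene Ackr2, Efhd1, the decoy receptor gene Il1r2, Cadm3, Akr1c18, the interferon-induced gene Ifi27l2a and Ly6c1 itself. On the lower side at -3.94 to -4.59 were Pla2g7, the retinoid genes Crabp1 and Stra6, the Fc receptor gene Fcgr2b, Col26a1, Megf6, the laminin gene Lamc3 and the vessel-destabilising factor gene Angpt2. Il6 was higher in icaf (1.12, SE 0.20, adjusted p = 0.00122) and Col1a1 lower (-1.17, SE 0.26, adjusted p = 0.00513). Cell cycle inhibitor genes Cdkn2b, Cdkn2a and Cdkn1a were lower in icaf. Cdkn2b (chromosome 4, 89306299 to 89311039) stood at 6.63 ± 4.17 CPM in icaf and 5.92 ± 0.540 in vcaf against 59.9 ± 12.5 in m2cafneg and 82.7 ± 4.39 in m2cafpos (icaf contrast -3.35, SE 0.25, adjusted p = 2.25e-06). Its neighbour Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653), which encodes p16 and p19ARF, was read in few copies, 6 to 16 reads per icaf library against 22 to 115 per m2cafneg or m2cafpos library (-1.07, SE 0.19, adjusted p = 0.00111). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), which encodes p21, stood at 100.3 ± 11.9 CPM in icaf, 135 ± 23.03 in m2cafneg and 184 ± 8.62 in m2cafpos (-0.65, SE 0.13, adjusted p = 0.00229). Acta2 was lower in icaf (-1.55, SE 0.37, adjusted p = 0.00775), a call that ended without the icaf library of mouse 30 (adjusted p = 0.0546). Epcam (-1.19, SE 0.43) had an adjusted p of 0.0601, and 0.00334 with the mouse as a block. Pecam1 (-1.08, SE 0.58) had 0.193, and 0.00273 with the block.

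All 15 genes of the universal Pi16 fibroblast list were higher in icaf (median 3.12, camera adjusted p = 3.16e-15 preset, 0.154 estimated), among them Cd55 (3.39) and Efhd1 (4.58). Of 19 inflammatory CAF genes 11 were higher, 1 lower and 7 not past the test (camera adjusted p = 4.01e-05 preset, 0.241 estimated). Members included Cxcl1 at 1.51, Gsn at 2.23 and Dpt at 2.41. Of 16 complement genes 8 were higher, 3 lower and 5 not past the test (camera adjusted p = 0.0147 preset, 0.431 estimated, and 0.0568 at the preset correlation without icaf 31). Members included C4b at 2.87 and Cfb at 2.58. Of 25 MHC class I and interferon genes 11 were higher, 1 lower and 13 not past the test (camera adjusted p = 0.000428 preset, 0.431 estimated). Members included Usp18 at 2.16, Oas1a at 1.76 and Bst2 at 1.04. In these 4 lists 15, 15, 9 and 15 members were higher adjusted over the list alone. Chemokine and cytokine genes (7 of 21 higher, 2 lower, 12 not past the test) included the B cell attractant gene Cxcl13 at 3.55 and Cx3cl1 at -2.39 (camera adjusted p = 0.101 preset, 0.560 estimated). Growth factor genes (8 of 21 higher, 3 lower, 10 not past the test) included Fgf7 at 2.17 and Fgf2 at 2.12 (camera adjusted p = 0.166 preset, 0.431 estimated). BMP and Wnt genes (8 of 26 higher, 6 lower) included Bmp6 at 2.87, Chrdl1 at 3.32 and Dkk3 at -2.23, with a median of -0.14 against a mean of 0.46 and a test that pointed higher (camera adjusted p = 0.318 preset, 0.542 estimated). Hypoxia and glycolysis genes (6 of 21 higher, 15 not past the test) had a median of -0.01, which was 0.04 with median-of-ratios scaling, and a mean of 0.08 (camera adjusted p = 0.29997 preset, 0.711 estimated), with Pfkp at 1.02. Adjusted over the list alone 8 chemokine, 10 growth factor, 11 BMP and Wnt and 6 hypoxia genes were higher.

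Contractile, chondro-osteogenic, senescence, matricellular and Notch lists were called lower in icaf by camera at the preset correlation, and none of these calls held with an estimated correlation. Of 15 myofibroblast contractile genes 9 were lower, 1 higher and 5 not past the test (camera adjusted p = 0.00268 preset, 0.431 estimated). Members included Mylk at -2.26 and Postn at -1.85. Of 15 chondro-osteogenic genes 10 were lower, 1 higher and 4 not past the test, with Runx2, a bone transcription factor gene, at -2.04 and Chad at -2.18 (camera adjusted p = 0.000269 preset, 0.241 estimated). Of 20 cell cycle arrest and senescence genes 9 were lower, 1 higher and 10 not past the test, including Cdkn2a and Cdkn2b, with a camera adjusted p of 0.00268 and adjusted p = 0.241 with an estimated correlation. Of 21 matricellular genes 9 were lower, 4 higher and 8 not past the test (camera adjusted p = 0.0225 preset, 0.431 estimated, and 0.0559 at the preset correlation without m2cafneg 27). Members included Ccn4 at -2.42. Of 12 Notch genes 4 were lower, 1 higher and 7 not past the test (camera adjusted p = 0.0271 preset, 0.431 estimated). Members included Heyl at -3.74 and Notch1 at -1.77. In these 5 lists 9, 12, 9, 10 and 4 members were lower adjusted over the list alone. Lists with members lower and no call by camera were fibrillar collagens (8 of 20 lower, 3 higher, camera adjusted p = 0.0914), basement membrane (9 of 19 lower, 5 higher, 0.166), matrix remodelling (9 of 20 lower, 3 higher, 0.101), pericyte (8 of 18 lower, 4 higher, 0.104) and vascular smooth muscle (6 of 15 lower, 1 higher, 0.194). Examples were Col11a1 (-3.39), Lama1 (-3.83), Mmp11 (-2.57), Cspg4 (-2.63) and Itga8 (-1.83). Their lower members adjusted over the list alone numbered 8, 9, 10, 8 and 6.

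Macrophage and epithelial sums in icaf were near those of m2cafpos and far below those of m2cafneg. Of 17 macrophage genes 16 were lower and 1 not past the test (camera adjusted p = 5.87e-07 preset, 0.427 estimated), and of 20 epithelial genes 7 were lower and 13 not past the test (camera adjusted p = 0.000358 preset, 0.560 estimated). Of 9 genes of the MHC class II list 6 were lower and 3 not past the test, with Cd74 at -1.31 and H2-Aa at -1.30 and with Slpi, a protease inhibitor gene placed on that list, at -1.67 (camera adjusted p = 0.0126 preset, 0.431 estimated). Dissociation stress genes (7 of 16 lower, 1 higher, 8 not past the test) included Jun at -0.64 and Fosb at -0.78 (camera adjusted p = 0.0769 preset, 0.560 estimated). Of 18 genes for ligands that act on NK and T cells 4 were higher and 5 lower, with the ectonucleotidase gene Nt5e at 3.16 against Tgfb3 at -1.73 and Tgfb1 at -1.40 (camera adjusted p = 0.654 preset, 0.779 estimated). Secretory phenotype factors were split (6 of 28 higher, 7 lower) with a median of -0.06, a mean of -0.15 and a test that pointed higher (camera adjusted p = 0.997 preset, 0.998 estimated). None of 26 proliferation genes passed (median 0.04, camera adjusted p = 0.902 preset, 0.998 estimated, 0 genes by median-of-ratios scaling, edgeR or DESeq2, and 0 at an unadjusted limma p under 0.05). Adjusted over the list alone 17 macrophage, 11 epithelial, 7 MHC class II, 9 stress, 6 ligand and 7 secretory genes were lower.

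In total 4063 genes differed between icaf and the mean of m2cafneg and m2cafpos in limma, 1872 higher and 2191 lower, 1567 of them by at least 2-fold. The count was 2580 without icaf 27, 2541 without icaf 30 and 1852 with the epithelial marker score as a covariate, with which the camera call of the Notch list ended (adjusted p = 0.171).

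Within the Ly6C-negative, PDGFRa-positive gate, camera at the preset correlation called fibrillar collagen, matricellular, matrix remodelling and contractile lists higher in NCAM-positive cells and MHC class II, complement, stress and hypoxia lists lower together with markers of other cells. All 14 list calls of this comparison were lost with an estimated correlation, and basement membrane genes had 0 of 19 higher. Ncam1 itself was higher in m2cafpos (log2 fold change 4.20, SE 0.14, limma adjusted p = 9.14e-09). C1qtnf3, a secreted C1q and TNF-related gene, was at 1531 ± 305 CPM in m2cafpos and 120 in m2cafneg (3.65, SE 0.37, adjusted p = 0.000249), and the matricellular gene Tnc was at 1693 ± 571 and 253 ± 100.5 CPM (2.76, SE 0.50, adjusted p = 0.00343). Lower in m2cafpos were the lysophospholipase gene Enpp2, which encodes autotaxin (-3.79, SE 0.52, adjusted p = 0.00125), and the ligand gene Bmp4 (-3.27, SE 0.27, adjusted p = 7.33e-05). The comparison asks how NCAM-positive and NCAM-negative cells of 1 gate differ.

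Further genes with the largest differences were, higher in m2cafpos at 2.75 to 3.10, Prss35, the gelatinase gene Mmp9, Ecrg4, the ERBB ligand gene Nrg1, the prokineticin receptor gene Prokr2, Adamts16 and Col8a2. Lower at -2.98 to -4.20 were Myoc, Inmt, Vtn, Angptl7, Scg3, Vit, the interferon-induced gene Ifitm1 and the complement gene C7. Acta2 was higher in m2cafpos (1.89, SE 0.42, adjusted p = 0.00863). Col1a1 was at 101468 ± 7685 CPM in m2cafpos and 48596 ± 8644 in m2cafneg (1.07, SE 0.30, adjusted p = 0.0217), a call that ended without m2cafneg 31 (adjusted p = 0.0728) or m2cafpos 27 (0.0621). Cdkn1a was higher by 0.46 (SE 0.15, adjusted p = 0.0375), a call that ended without m2cafneg 27 (0.110), m2cafneg 30 (0.1001), m2cafpos 27 (0.0936), m2cafpos 30 (0.0673) or m2cafpos 31 (0.104). Cdkn2b (0.48, SE 0.29, adjusted p = 0.248) and Cdkn2a (0.54, SE 0.22, adjusted p = 0.0853) did not pass, and Cdkn2a had an adjusted p of 0.0309 with median-of-ratios scaling and 0.385 with edgeR. Il6 (-0.18, SE 0.23, adjusted p = 0.599) and Pdgfra (-0.09, SE 0.17, adjusted p = 0.721) did not pass, and with median-of-ratios scaling both values were positive (0.09 and 0.19). Ly6c1 (-0.63, SE 0.28) had an adjusted p of 0.112, and 0.0334 with the mouse as a block.

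Of 20 fibrillar collagen and assembly genes 10 were higher in m2cafpos, 1 lower and 9 not past the test (camera adjusted p = 3.38e-14 preset, 0.0510 estimated). Members included Col12a1 at 2.21, the prolyl hydroxylase gene P4ha3 at 2.32 and Fmod at 1.94. Of 21 matricellular and TGF-beta response genes 12 were higher, 1 lower and 8 not past the test (camera adjusted p = 1.95e-10 preset, 0.0510 estimated). Members included Cthrc1 at 1.98, Ltbp2 at 2.02 and Aspn at 1.13. Of 20 matrix remodelling enzymes 7 were higher, 1 lower and 12 not past the test (camera adjusted p = 1.81e-06 preset, 0.0510 estimated). Members included Timp1 at 1.45 and Mmp23 at 1.11. Of 15 myofibroblast contractile genes 8 were higher, 2 lower and 5 not past the test (camera adjusted p = 6.91e-07 preset, 0.271 estimated). Members included Tagln at 1.43, Tpm2 at 0.97 and Cnn2 at 0.97 against Lmod1 at -1.31. Higher members of these 4 lists adjusted over the list alone numbered 13, 12, 7 and 9. With the epithelial covariate 1, 3, 0 and 1 were higher and the preset camera calls held. Medians were 0.34, 0.74, 0.33 and 0.64, from 0.71, 0.89, 0.32 and 0.48.

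Of 9 genes of the MHC class II list, Slpi and Saa3 included, 7 were lower in m2cafpos and 2 not past the test, with Cd74 at -2.56 and H2-Aa at -2.45 (camera adjusted p = 0.000104 preset, 0.271 estimated). Beside them 16 of 17 macrophage genes (camera adjusted p = 1.95e-10 preset, 0.239 estimated) and 19 of 20 epithelial genes (camera adjusted p = 1.81e-06 preset, 0.456 estimated) were lower. Of 16 complement genes 9 were lower, 1 higher and 6 not past the test, with Clu at -2.24 and with C1qa (-2.08) and C1qb (-2.23), which the macrophage list also holds, and with median-of-ratios scaling 5 were lower. Its camera adjusted p was 0.0301, adjusted p = 0.456 with an estimated correlation, and the call ended without m2cafneg 30 (0.121) or m2cafpos 27 (0.0510). Of 16 dissociation stress genes 15 were lower and 1 not past the test, with Atf3 at -1.52 and Nr4a1 at -1.23, and with median-of-ratios scaling 10 were lower (camera adjusted p = 8.45e-07 preset, 0.239 estimated). Of 21 hypoxia and glycolysis genes 11 were lower and 10 not past the test, with Ndrg1 at -1.39 and Pfkl at -1.45, and with median-of-ratios scaling 6 were lower. Its camera adjusted p was 0.0440, adjusted p = 0.584 with an estimated correlation, a call that ended without icaf 31 (0.0575), m2cafneg 27 (0.0766), m2cafneg 31 (0.0874) or m2cafpos 30 (0.108). Endothelial genes (12 of 20 lower, 8 not past the test, and 3 lower with median-of-ratios scaling) had a camera adjusted p of 0.0319, adjusted p = 0.676 with an estimated correlation, a call that ended without m2cafneg 31 (0.145) or m2cafpos 27 (0.125). Adjusted over the list alone 8 MHC class II, 16 macrophage, 20 epithelial, 10 complement, 16 stress, 11 hypoxia and 14 endothelial genes were lower.

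Of 18 genes for ligands that act on NK and T cells 7 were lower in m2cafpos and 2 higher, with the ectonucleotidase genes Entpd1 (-1.74) and Nt5e (-2.30), which act in adenosine production, among the lower, and with median-of-ratios scaling 3 were lower and 3 higher (camera adjusted p = 0.997 preset, 0.999 estimated). Of 15 universal Pi16 fibroblast genes 8 were lower and 2 higher, with Efhd1 at -1.91 and Mfap5 at 0.90, and with median-of-ratios scaling 1 was lower and 2 higher (camera adjusted p = 0.997 preset, 0.999 estimated). MHC class I and interferon genes (7 of 25 lower, 18 not past the test) gave 0 lower and 1 higher with median-of-ratios scaling (camera adjusted p = 0.804 preset, 0.999 estimated). Of 20 cell cycle arrest and senescence genes 5 were higher, among them Igfbp3 at 1.64, and 5 lower, among them Bcl2l1 at -1.19 and Ccnd1 at -1.40, with a median of -0.07 that was 0.18 with median-of-ratios scaling and a test that pointed higher (camera adjusted p = 0.0589 preset, 0.346 estimated). With that scaling 6 were higher and 2 lower. Inflammatory CAF genes (6 of 19 higher, 5 lower) included Svep1 at 0.95 and Cxcl12 at -1.65, with a median of -0.18 that was 0.09 with median-of-ratios scaling and a test that pointed higher (camera adjusted p = 0.0655 preset, 0.559 estimated). BMP and Wnt genes (3 of 26 higher, 8 lower) included Dkk3 at 0.95 and Chrdl1 at -2.05 (median -0.17, test pointing higher, camera adjusted p = 0.733 preset, 0.814 estimated). Basement membrane genes (6 of 19 lower) included Col18a1 at -1.16 and Nid2 at -0.91 (camera adjusted p = 0.604 preset, 0.861 estimated). The lower members of these 7 lists adjusted over the list alone numbered 8, 8, 7, 7, 5, 9 and 7.

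Camera called secretory, chemokine and growth factor lists higher than other genes at the preset correlation alone, and median-of-ratios scaling ended each call. Secretory phenotype factors (4 of 28 higher and 5 lower, or 5 and 1 with that scaling) had an adjusted p of 0.0217 (adjusted p = 0.346 with an estimated correlation, 0.145 without m2cafneg 31 and 0.0558 without m2cafpos 27). Chemokine and cytokine genes (4 of 21 higher, 4 lower) had 0.0208 (adjusted p = 0.456 with an estimated correlation, 0.210 without m2cafneg 31, 0.0535 without m2cafpos 27 and 0.0510 without m2cafpos 30). Growth factor genes (3 of 21 higher, 2 lower), with Pdgfd at 1.04 and Pdgfc at -1.03, had 0.0473 with a median of -0.08 and a mean of 0.07 (adjusted p = 0.271 with an estimated correlation, 0.0515 without icaf 31, 0.275 without m2cafneg 31, 0.0613 without m2cafpos 27 and 0.162 without m2cafpos 30). The pericyte list (2 of 18 higher and 4 lower, or 2 and 1 with that scaling, camera adjusted p = 0.997), the vascular smooth muscle list (2 of 15 higher, 4 lower, 0.804), the chondro-osteogenic list (3 of 15 higher, 3 lower, 0.183, with Sox9 at -2.08) and the Notch list (1 of 12 lower, 0.804) were not called. Of 26 proliferation genes 0 passed in limma, edgeR, DESeq2 or with median-of-ratios scaling and 1 had an unadjusted limma p under 0.05 (median -0.55, camera adjusted p = 0.894). The pericyte and smooth muscle medians were -0.70 and -0.19 while the test pointed higher. The chondro-osteogenic list had a median of 0.08 and a mean of -0.16. Adjusted over the list alone the higher and lower counts were 4 and 6 (secretory), 4 and 4 (chemokine) and 3 and 2 (growth factor).

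In total 4041 genes differed between m2cafpos and m2cafneg in limma, 542 higher and 3499 lower, 1392 of them by at least 2-fold. With median-of-ratios scaling, which moved the median log2 fold change of all genes from -0.23 to 0.01, there were 1291 higher and 1314 lower genes. With the epithelial covariate 189 genes passed, among them Ncam1, C1qtnf3, Tnc and Bmp4, while 64 of the 96 genes named here with a call lost it. Camera calls then ended for the complement (adjusted p = 0.0563, median -0.71 from -0.68), hypoxia (0.344, -0.27 from -0.64), secretory (0.722) and growth factor lists (0.753). Those of the chemokine (0.722) and endothelial lists (0.677) ended and pointed the other way. Without m2cafneg 31, m2cafpos 27 or m2cafpos 30 limma gave 2399, 2241 or 2586.

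The remaining lists of other cell types were tested in the same way, gene by gene, so an abundant member such as Pmp22 can set a sum that most members do not follow. In vcaf, 5 of 8 lymphocyte genes were higher and 3 not past the test (camera adjusted p = 0.578), 10 of 15 Schwann genes higher and 4 lower (0.382), 3 of 8 adipocyte genes higher and 1 lower (0.670) and 4 of 6 erythroid genes higher (0.277, and 1 with median-of-ratios scaling). Of 5 neutrophil genes 3 were higher and 2 lower in vcaf, with a median of 0.64 and a mean of 0.24 and a test that pointed lower (0.382). Of 5 skeletal muscle genes 3 were lower in vcaf (camera adjusted p = 0.00425 preset, 0.264 estimated), and of 2 mesothelial genes, too few for camera, 1 was higher and 1 lower. In icaf against m2cafneg and m2cafpos, 3 of 8 lymphocyte genes were lower (camera adjusted p = 0.101), 1 of 5 neutrophil genes higher and 3 lower (0.549, median -1.04 and mean 0.05) and 2 of 15 Schwann genes higher and 2 lower (0.963, median -0.15 and mean 0.09). There 1 of 8 adipocyte genes was lower (0.654), and 2 of 20 endothelial genes were higher and 6 lower (0.101). None of 5 skeletal muscle (0.997), 6 erythroid (0.184) or 2 mesothelial genes passed there in limma, with 0, 2 and 1 at an unadjusted p under 0.05 and 0, 0 and 1 by edgeR and by DESeq2. In m2cafpos against m2cafneg, 3 of 8 lymphocyte (camera adjusted p = 0.665), 8 of 15 Schwann (0.133), 3 of 8 adipocyte (0.442), 1 of 5 skeletal muscle (0.889) and 3 of 6 erythroid genes (0.118, and 0 with median-of-ratios scaling) were lower and none of them higher. Of 5 neutrophil genes 1 was higher and 1 lower (0.927, median -0.42, test pointing higher), and of 2 mesothelial genes 1 was higher and 1 lower. The 9 genes of the sort gates, which were chosen to differ between gates, were not called as a list in the vcaf, icaf and m2cafpos comparisons (camera adjusted p = 0.104, 0.513 and 0.889), with 5, 2 and 1 members higher and 4, 3 and 3 lower. Their medians of 1.19, -0.75 and -0.63 and means of 0.10, 0.15 and -0.38 stood beside tests that pointed lower, lower and higher. Counts higher and lower adjusted over the list alone for neutrophil genes were 3 and 2 in vcaf, 1 and 3 in icaf and 1 and 2 in m2cafpos, and for Schwann genes 10 and 4, 2 and 2, and 1 and 8.

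**Figure D4:**
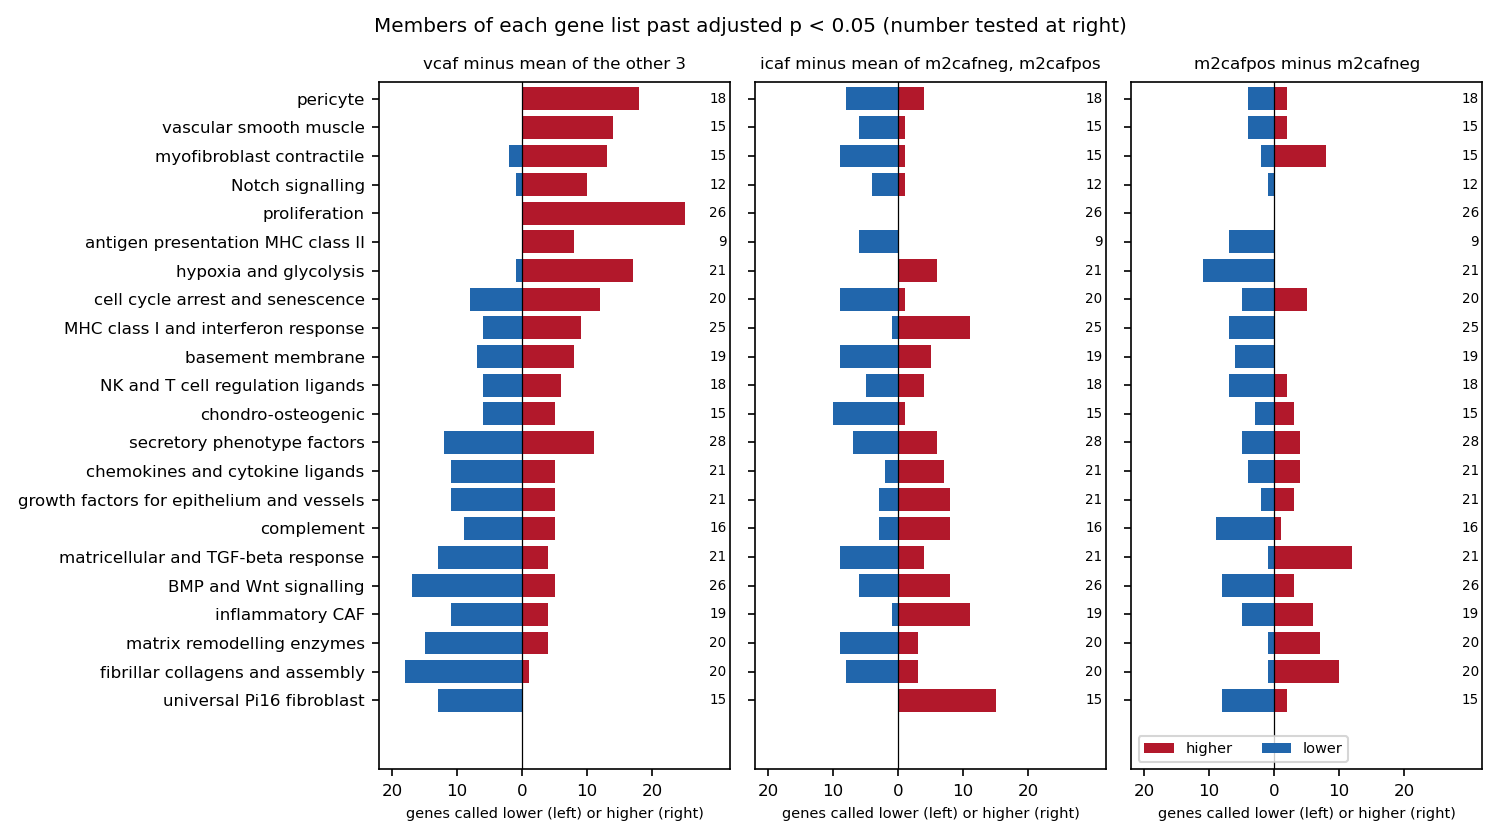
Members of 22 gene lists called higher (right, red) or lower (left, blue) by limma in each of the 3 main comparisons, with the number of genes on the horizontal axis and the number tested at the right. In vcaf all 18 pericyte genes are higher and 18 of 20 fibrillar collagen genes lower, in icaf all 15 universal Pi16 fibroblast genes are higher, and in m2cafpos 12 of 21 matricellular genes are higher, while for MHC class I and interferon genes the m2cafpos bar of 7 lower becomes 1 higher with median-of-ratios scaling.

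Each population also had genes above all 3 others. For icaf there were 733, led by the sphingomyelinase gene Smpd3 (52.8 ± 5.46 CPM against 1.24 ± 1.22 in m2cafneg, the next population), Sema3c (394 against 14.8), Il1r2 (135 against 4.97), Ifi27l2a (124 against 6.36) and the lubricin gene Prg4 (160 against 8.36). For m2cafneg there were 63, led by Angptl7 (28.6 ± 26.9 against 1.62 ± 1.29 CPM), Fam180a (45.5 against 7.22), the neprilysin gene Mme (47.0 against 9.64), Enpp2 (289 ± 264 against 51.4) and Entpd1 (159 against 49.7). With the mouse as a block 115 genes were above all others in m2cafneg, and with median-of-ratios scaling 30 were. Without m2cafpos 27 or m2cafpos 31 the m2cafneg count was 37 or 39. For m2cafpos there were 265, led by C1qtnf3 (1531 against 141 in icaf), Ecrg4 (124 against 15.3 in m2cafneg), Prokr2 (61.8 against 10.1), Tnc (1693 against 253) and Col8a2 (146 against 20.7). With median-of-ratios scaling the m2cafpos count was 532, and without m2cafpos 27 or m2cafpos 31 it was 155 or 173. For vcaf there were 3301, led by Rgs5 (41419 against 157 in m2cafneg), Higd1b (505 against 1.81), Olfr558 (288 against 0.929), Serpina1b (349 against 2.17) and Rasl12 (266 against 1.85). The vcaf count was 1066 with median-of-ratios scaling and 2093 without vcaf 27. With the epithelial covariate the counts were 132 for icaf, 2 for m2cafneg, 50 for m2cafpos and 1161 for vcaf, and edgeR gave 19 for m2cafneg and 947 for vcaf.

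Pairwise comparisons gave 4594 genes for icaf against m2cafneg (1356 higher, 3238 lower), 3692 for icaf against m2cafpos (2322 higher, 1370 lower) and 9265 for icaf against vcaf (2147 higher, 7118 lower). Against vcaf, m2cafneg had 5861 genes (1752 higher, 4109 lower) and m2cafpos 10492 (1915 higher, 8577 lower). With median-of-ratios scaling the higher and lower counts were 2091 and 2532, 1511 and 1797, and 3763 and 3701 for icaf against m2cafneg, m2cafpos and vcaf, and 2416 and 1499 for m2cafneg and 3623 and 3491 for m2cafpos against vcaf. The same scaling moved the median log2 fold change of all genes in these 5 comparisons from -0.12, 0.11, -0.36, -0.26 and -0.51 to within 0.02 of 0. With the epithelial covariate the counts fell to 386 for icaf against m2cafneg, 2485 for icaf against vcaf and 4021 for m2cafpos against vcaf. Cdkn2b was lower in icaf than in m2cafneg (-3.11, adjusted p = 2.14e-05) and m2cafpos (-3.59, adjusted p = 4.37e-06) and higher in m2cafneg (3.12, adjusted p = 4.55e-06) and m2cafpos (3.599, adjusted p = 8.79e-07) than in vcaf, each with SE 0.29. Cdkn2a was lower in icaf than in m2cafpos (-1.34, SE 0.22, adjusted p = 0.000678) and higher in m2cafpos than in vcaf (1.31, SE 0.22, adjusted p = 0.000237). The differences of m2cafneg from icaf (-0.80, adjusted p = 0.0148) and from vcaf (0.77, adjusted p = 0.0154) in Cdkn2a passed in limma and not in edgeR (adjusted p = 0.0637 and 0.0578). Cdkn2a had 0 reads in the vcaf library of mouse 27, and a count of 0 allows up to 3 reads.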

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

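The tests with edgeR, DESeq2, the epithelial covariate, the covariate with median-of-ratios scaling, and mice 27 and 30 only were chosen after the results were seen. With 3 libraries per population, simulated 2-fold changes were recovered for 25% to 71% of genes in limma, so smaller differences may have gone uncalled. Library totals bound counting error only. With a pseudocount of 5, a filter at 5 CPM, limma without the trend and fits of only the 2 groups compared, every count stayed within 1.5 times of its value, and of 312 gene results named 1 lost its call without the trend and 17 fell below that filter. Of 47 list calls a pseudocount of 5 ended 4 and that filter 8. With the mouse as a block more genes were called in the 3 main comparisons (10933, 5099 and 5128, from 10431, 4063 and 4041). With that block the 312 named gene results that had a call and 47 of 47 list calls kept it, Epcam and Pecam1 in icaf and Ly6c1 in m2cafpos against m2cafneg gained a call, 99.6% to 99.9% of the calls of each comparison were shared, and the count specific to m2cafneg moved to 115. With a pseudocount of 0.1 that count was 39 and 2 list calls ended. Without a filter, where more genes were tested, m2cafpos against m2cafneg gave 2617, and 12 gene and 5 list calls ended.

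With median-of-ratios scaling the counts that moved were 2605 for m2cafpos against m2cafneg and 30, 532 and 1066 genes specific to m2cafneg, m2cafpos and vcaf. It shared 55.2% of the calls in the vcaf comparison (21 more changed direction), 98.7% in the icaf comparison and 45.9% in m2cafpos against m2cafneg, and ended 14 gene and 6 list calls. These shifts follow from its construction, which lowers vcaf and raises m2cafpos values by a single factor per library. The counts were 2088, 3758 and 6913 with edgeR for m2cafpos against m2cafneg, m2cafneg against vcaf and m2cafpos against vcaf, with 19 and 947 genes specific to m2cafneg and vcaf. With the block, edgeR gave 38, 534 and 1142 genes specific to m2cafneg, m2cafpos and vcaf, and DESeq2 gave 35, 564 and 1065. These 3 count-based tests ended 13, 7 and 10 gene calls. They also scale the libraries, so they are not independent of median-of-ratios scaling. In vcaf edgeR gave 3665 higher and 3583 lower genes, near the 3566 and 3852 with that scaling and unlike the 8238 and 2193 without it. Other causes of the lost calls were not tested.

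With the epithelial score as a covariate the counts were 4335 for vcaf, 1852 for icaf, 189 for m2cafpos against m2cafneg, 386 and 2485 for icaf against m2cafneg and vcaf, and 4021 for m2cafpos against vcaf, with 132, 2, 50 and 1161 genes specific to icaf, m2cafneg, m2cafpos and vcaf. It shared 40.4%, 43.9% and 4.01% of the calls in the 3 main comparisons and ended 84 gene and 8 list calls. With median-of-ratios scaling added they were 2883, 1966, 118, 359, 2068 and 2381 in the same order, 3849 for m2cafneg against vcaf, and 153, 2, 69 and 511 specific genes. Genes of the epithelial list make up this covariate, so their values with it are circular and were not counted. With mice 27 and 30 only, m2cafpos against m2cafneg gave 1786, icaf against m2cafneg 2982 and icaf against m2cafpos 2389, with 446, 35 and 126 genes specific to icaf, m2cafneg and m2cafpos, and 18 gene and 8 list calls ended, on 8 libraries. Requiring a log2 fold change of at least 1 left 3452, 1567 and 1392 genes in the main comparisons, 2212, 1542 and 4286 for icaf against m2cafneg, m2cafpos and vcaf, 2120 and 4447 for m2cafneg and m2cafpos against vcaf, and 404, 23, 111 and 931 specific genes.

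Leaving out each library in turn gave 8931 to 10485 genes for vcaf, 2541 to 4273 for icaf, 2241 to 4219 for m2cafpos against m2cafneg, 3166 to 4755, 2636 to 3852 and 8031 to 9356 for icaf against m2cafneg, m2cafpos and vcaf, and 4172 to 5998 and 9390 to 10578 for m2cafneg and m2cafpos against vcaf. Specific genes ranged over 503 to 784 (icaf), 37 to 70 (m2cafneg), 155 to 272 (m2cafpos) and 2093 to 3602 (vcaf). Counts moved by more than 1.5 times for icaf without icaf 27 (2580) or 30 (2541), and for m2cafpos against m2cafneg without m2cafneg 31 (2399), m2cafpos 27 (2241) or 30 (2586). So did specific genes of m2cafneg without m2cafpos 27 (37) or 31 (39), of m2cafpos without m2cafpos 27 (155) or 31 (173), and of vcaf without vcaf 27 (2093).

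Psmb8 in the vcaf comparison changed sign with median-of-ratios scaling (-0.038), edgeR (-0.031), edgeR with the block (-0.031), DESeq2 (-0.038) and the scaling with the covariate (-0.073). The last setting also reversed Cdkn1a in the vcaf comparison (-0.12) and Bcl2l1 (0.11), Pfkl (0.014) and Clu (0.014) in m2cafpos against m2cafneg. There camera pointed the other way for chemokines with the covariate (median -0.25) and with both (-0.013), for endothelial genes with the covariate (-0.21), and for secretory (-0.013) and growth factors (0.035) with both. The cause was not tested. Of 47 list calls, 41 were lost with an estimated correlation.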

Other observations

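All tests here were chosen after the results were seen, except the scaling test of the proliferation genes and the set test of transcription factor and receptor lists. The transcription factors and receptors named were chosen after their values were seen, from 69 and 92 tested genes. In vcaf the hypoxia-inducible factor gene Epas1 stood at 633 CPM against 18.4 in icaf, 50.5 in m2cafneg and 36.8 in m2cafpos (log2 fold change 4.29, SE 0.24, limma adjusted p = 1.89e-08). The nuclear receptor gene Nr2f2 was higher as well (3.63, SE 0.19, adjusted p = 1.21e-08), with Tbx2 (3.26), Mef2c (3.09), the smooth muscle coactivator gene Myocd (3.01) and Foxs1 (2.96). Receptor genes higher in vcaf included Ednrb for endothelin (4.42, SE 0.54, adjusted p = 2.39e-05) and Avpr1a for vasopressin (3.36, SE 0.22, adjusted p = 9.16e-08), with S1pr3 for sphingosine phosphate (2.41) and the fatty acid transporter gene Cd36 (3.96). Lower in vcaf were the odd-skipped genes Osr1 (-4.40, SE 0.12, adjusted p = 9.39e-11) and Osr2 (-3.14), Bnc2 (-3.62), Meox1 (-2.76) and Prrx2 (-2.18). Among receptor genes Lpar1 (-4.63, SE 0.14), Ntrk2 (-3.79), Il11ra1 (-3.07), Fgfr1 (-2.13) and Tgfbr2 (-2.90) were lower. Tgfbr2 stood at 79.3 CPM in vcaf against 454 to 870 in the others.

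In icaf, Procr and Thbd, which encode anticoagulant surface proteins, were higher than in m2cafneg and m2cafpos, with Procr at 111 CPM against 11.6 and 9.32 (3.25, SE 0.22, adjusted p = 1.04e-06) and Thbd at 363 against 59.0 and 88.2 (2.32, SE 0.19, adjusted p = 3.05e-06). The angiopoietin receptor gene Tek (3.08, SE 0.27, adjusted p = 6.01e-06), which the endothelial list also holds, the angiotensin receptor gene Agtr2 (3.36), the IL-33 receptor gene Il1rl1 (2.71), Npr1 (2.71) and Tshz2 (2.12) were higher too. Lower in icaf were the endothelin receptor gene Ednra at 29.4 against 230 and 267 CPM (-3.05, SE 0.31, adjusted p = 1.77e-05), Unc5b (-3.64), Ramp1 (-2.90) and Fzd1 (-2.04). Among transcription factor genes, those lower in icaf included Msx1 (-2.49, SE 0.24, adjusted p = 1.18e-05), Alx4 (-2.34), Runx1 (-2.32) and Runx2 (-2.04). In m2cafpos against m2cafneg the Wnt co-receptor gene Lgr5 was higher at 28.0 against 6.70 CPM (2.05, SE 0.48, adjusted p = 0.0108), and P2ry14 (-2.69), Kit (-2.38) and Sox9 (-2.08) were lower, in the direction of 19 of 20 epithelial genes. Kit and Sox9 were highest in vcaf and m2cafneg (113 and 88.5 CPM, and 108 and 81.6 CPM), as the epithelial markers were.

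As sets, 29 of 69 transcription factor genes were higher and 24 lower in vcaf, 14 and 19 in icaf, and 3 and 9 in m2cafpos. Of 92 receptor genes 38 were higher and 34 lower in vcaf, 32 and 30 in icaf, and 8 and 22 in m2cafpos. With median-of-ratios scaling the receptor counts became 28 and 42 in vcaf and 19 and 16 in m2cafpos, and those of transcription factors 21 and 26 in vcaf and 6 and 6 in m2cafpos. With an estimated correlation no list was called in any of the 3 comparisons, with a smallest camera adjusted p of 0.122. At the preset correlation the smallest was 0.000450, for receptors in vcaf, pointing lower while the median was 0.06.

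In m2cafpos against m2cafneg 3499 genes were lower and 542 higher. With median-of-ratios scaling 50.4% of the called genes were lower. That scaling sets the median of all genes near 0 by construction, so this balance does not decide whether scaling by library totals caused the uneven split, and the scaling and a real shift cannot be told apart. For RNA of epithelial cells, 2.74% of the 1314 genes called lower with that scaling (36 genes) stayed called with the epithelial score as a covariate, which met the mark set for this explanation, under 50%. The genes called higher lost their calls too (73 of 1291, 5.65%, stayed), a condition that was added after the result was seen and that leaves the test without weight. The median log2 fold change went from -1.15 to -0.43 for lower genes (SE 0.26 to 0.36) and from 0.73 to 0.64 for higher genes (SE 0.17 to 0.28). The score differs between both populations, which widens the SE, but whether epithelial RNA caused the larger fall among lower genes was not tested apart from population, and both cannot be told apart for these genes.

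Of 26 proliferation genes 25 were higher in vcaf, and 20 with median-of-ratios scaling, against scaling as the whole cause. From the line through m2cafpos and m2cafneg at the epithelial level of vcaf, the summed CPM of the list in vcaf was 3.34 times the expected value in mouse 27, 1.33 in mouse 30 and 1.42 in mouse 31. In mouse 27 the line was flat (373 in m2cafneg and 376 in m2cafpos), and icaf, with the lowest epithelial sum of that mouse (1314), had 635 CPM of the list, which goes against an epithelial source in that mouse. The lowest of these, 1.33, lies between the marks of 1 and 1.5, so dividing stromal cells and RNA of dividing tumour cells cannot be told apart. EPCAM-positive cells were gated out, yet Csn3 stood at 5252 CPM in vcaf. With the epithelial covariate 3 genes were called (median log2 fold change 0.88, from 1.35), and with the scaling added 1 (0.51).

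Cdkn2b and Cdkn2a were highest in m2cafpos and m2cafneg. Cdkn2b in vcaf, where epithelial markers were highest, was at most 0.134 times its level in m2cafneg over the 3 mice, which RNA of epithelial cells as the source does not allow. The smallest of the 4 log2 fold changes of Cdkn2b against icaf and vcaf was 2.99 with median-of-ratios scaling, far above the shift that scaling gives. Cdkn2b had 2073 to 4802 reads in each m2cafneg or m2cafpos library and 165 to 570 in each icaf or vcaf library, and Cdkn2a 22 to 115 and 0 to 28. The 2 populations may thus hold more Cdkn2b RNA as a property of their cells, a hypothesis found and tested on the same libraries, and whether these cells were senescent was not tested.

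Other splits of the libraries were counted for each number of genes called, with 100 draws from all splits and 100 from those that keep each population once in each mouse, as the real one does. For vcaf the real split alone (1 of 100 and 1 of 100) gave as many as 10431 genes (highest other 3074 over all splits and 6834 within mice). For icaf 1 of 100 and, within mice, 2 of 100 gave as many as 4063 (highest other 2311 and 4275), the other being 1 that put the m2cafneg libraries under the name. Genes specific to icaf numbered 733 (1 and 1 of 100, highest other 22 and 447), to m2cafneg 63 (1 and 2 of 100, highest other 0 and 1947) and to vcaf 3301 (1 and 1 of 100, highest other 0 and 2028). For these 5 counts at most 2 of 100 splits, the real one included, gave as many. The populations were sorted to differ, and mixed splits called few genes (median 0 over all splits), so these shares do not exclude chance. For m2cafpos 5 of 100 splits gave at least 265 specific genes (highest other 2317), so chance was not excluded by that count either, while within mice 2 of 100 did (highest other 2028). Of the other splits as large, those for m2cafpos put all 3 libraries of vcaf (2272, 2317 and 2028) or of icaf (313 and 321) under that name, and that for m2cafneg those of vcaf, which points to the structure of the samples. In the 6 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real counts were 4041 for m2cafpos against m2cafneg, 4594, 3692 and 9265 for icaf against m2cafneg, m2cafpos and vcaf, and 5861 and 10492 for m2cafneg and m2cafpos against vcaf, with a highest other of 1 for m2cafneg against vcaf and 0 for the rest.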
